A study of Arabidopsis thaliana with 8 samples.

How the data were processed

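Transcript levels were measured in whole seedlings of Arabidopsis thaliana at 7 days of age, with 1 Affymetrix ATH1 array per RNA sample. ATH1 is a short-oligonucleotide array on which a set of probes, the probe set, reports 1 transcript or a few related ones. The 8 arrays formed 4 groups of 2, labelled as biological replicates: the Col-0 wild type and the bbx24-1 mutant, each in white light and in simulated shade.

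The deposited value table held linear signal intensity for 22746 probe sets, and the column names of a shorter deposited table give the signal as MAS5, per the file headers. The series text says that the authors normalized the data, left out probe sets called absent with a signal under 50 in all replicates, and used Significance Analysis of Microarrays (SAM). The scaling target and software version are not given in the sources used here. Median signal lay between 212 and 220 on the 8 arrays, with nearly equal quartiles, and the correlation of log2 signals between 2 arrays ran from 0.965 to 0.984. No detection calls were used here. The authors' deposited table of 3255 selected probe sets carries no statistics. All 3255 had 8 values equal to those of the value table within 0.006 signal units.

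Signals were converted to log2(signal + 16), and 18391 probe sets with a signal of at least 50 on at least 1 array were tested. A fold change on this scale understates the change of weakly expressed genes. limma 3.58.1 in R 4.3.3 fitted the 4 group means with 1 shared estimate of the spread per probe set (4 residual degrees of freedom). The variances were moderated with a trend on mean signal (eBayes). Tests were two-sided and p-values were adjusted by the Benjamini-Hochberg method, with 0.05 as the threshold. The 7 contrasts were the shade effect in each genotype, their difference (the interaction), the genotype effect in each light treatment, and the average shade and average genotype effects. A moderated F test covered any difference between the 4 groups. For arrays, their number limits the precision: each group had 2.

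Gene names came from the platform's gene table, updated through gene numbers to the current gene records of the TAIR10.1 assembly. Of the 22746 probe sets, 13513 had 1 gene, 503 had several and 8730 had none listed in that table. Of the single-gene probe sets, 13436 matched a current record, of which 11885 carry only a locus number as their symbol. No coordinates are printed because the files name no genome build. Probe sets with several genes or none are counted in the totals and not named, apart from 1 probe set described by its values.

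Before the data were examined, 23 gene lists were fixed for light, hormone, growth, stress, root and seed functions. Of their 439 genes, 61 lay on a named probe set, and 4 lists had 5 or more: cell wall growth, chlorophyll biosynthesis, flavonoid and gibberellin. These 4 were tested in each contrast with camera at a preset inter-gene correlation of 0.01, with adjustment over all 28 tests, using the probe set with the highest mean for each gene. Members of the smaller lists are reported singly. The count of list members past the threshold is also given adjusted over the list alone. A signed fry test asked whether the genes called for the average shade effect moved, on balance, with or against that direction in the interaction and in the average genotype effect. Its p-values were adjusted together with those of 4 tests on rising and falling genes that were added after the data were seen.

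Genes to be named were also set by rule beforehand: BBX24 first, then in each contrast up to 8 largest rises and 8 largest falls among single-gene probe sets past the threshold whose groups did not overlap. For the average effects, non-overlap was required in the same direction within each treatment or genotype. Where fewer than 5 named probe sets passed, the 5 smallest p-values were taken and are stated as not passing. For each list, up to 4 members past the threshold with the largest change were taken, or the 2 largest changes as values where none passed. No probe set was named BBX24 or STO in the gene table, so the level of the mutated gene is not analysed here by name.

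The fits were tested on simulated data with the real means and the moderated variances of 18391 probe sets, drawn as independent normal values. Such data follow the variance model of the fit, so they cannot test that model or the effect of correlated genes. In the simulated average shade effect, 90 of 100 probe sets changed by 1 log2 unit and 98 of 100 changed by 2 were recovered. For the simulated interaction the recovered numbers were 51 of 100 and 83 of 100. False calls in single simulations numbered 23 for the average shade effect, 15 for shade in wild type, 13 for genotype in shade and 3 for the interaction, so the share of false calls can exceed the nominal level. Alternatives covered the pseudocount, the signal filter, quantile and median scaling, the variance model, a block for replicate number and fits on single pairs of groups. They also covered SAM-type relative differences with permutations, other set tests, and leaving out each array in turn. On a single pair of groups the SAM-type test used 4 arrays and 6 permutations, the real split and its mirror among them. It used 70 permutations for each average effect and 100 for any difference between the 4 groups. Its settings were chosen here, so its counts do not stand for the authors' SAM.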

Results

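The series compared seedlings of the Col-0 wild type with seedlings of bbx24-1, a mutant in BBX24 (also called STO), which encodes a B-box zinc finger protein of light signalling. Both genotypes were kept in white light or in simulated shade, the light environment of plants growing near neighbours, and RNA was profiled at 7 days of age. Each of the 4 groups had 2 arrays, and 18391 probe sets were tested. The series title places the question in genes of shade avoidance that BBX24 regulates. Median signal per array ran from 212 to 220, and the 2 replicates of a group correlated across probe sets at 0.973 to 0.984 on the log2 scale.

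BBX24 itself was carried by no named probe set, so its transcript level is not reported and the genotype labels were not checked by name. The probe set with the smallest genotype p has no gene listed in the gene table used. Its signal was 6108 ± 296 in wild type and 224 ± 99.0 in bbx24 in white light (mean ± SD, n = 2). In shade it was 5926 ± 654 in wild type and 161 ± 52.8 in bbx24. The differences, -4.73 ± 0.24 and -5.10 ± 0.24 (log2 ± SE), had limma adjusted p of 4.07e-07 and 1.52e-07. This probe set was singled out after its values were seen. Whether it reports BBX24 itself was not determined, and it is counted among the genotype calls in white light, in shade and on average.

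In the wild type, genes that rose with shade included IAA29, GH3.3 and YUC2. IAA29, an auxin-induced repressor of auxin signalling, rose from 161 ± 111 to 687 ± 120 (mean signal ± SD, n = 2), a log2 change of 2.14 ± 0.31 (SE; adjusted p = 0.0073). The change of IAA29 ran from 1.448 to 2.828 over the alternatives. Its call was lost without the signal filter, without a variance trend and with robust moderation. GH3.3, which encodes an auxin-conjugating enzyme, rose by 1.59 ± 0.18 on the log2 scale (adjusted p = 0.0016). YUC2, for auxin biosynthesis, rose by 1.06 ± 0.18 (adjusted p = 0.025). The call of YUC2 was lost without the signal filter and without a variance trend. It was also lost without wild-type white light replicate 2, wild-type shade replicate 1 or either bbx24 white-light array. Among named probe sets past the threshold, AT5G02580 had the largest rise, from 196 ± 7.43 to 998 ± 54.9 (adjusted p = 3.25e-05). AT2G34620 had the largest fall among these, from 1200.3 ± 6.27 to 509 ± 25.7, a log2 change of -1.21 ± 0.14 (adjusted p = 0.0016).

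In total 63 probe sets changed with shade in the wild type, 51 higher and 12 lower. AT5G02540 rose from 312 ± 78.8 to 1281 ± 162 (adjusted p = 0.00127). The other large rises among named genes were AT1G77200, AT5G12050, AT4G11610 and the thionin gene THI2.2, with log2 changes between 1.23 and 1.83. The call of AT5G12050 was lost only without a variance trend. Those of AT1G77200, AT4G11610 and THI2.2 were lost without the signal filter and without a variance trend. They were also lost without wild-type white light replicate 1 or wild-type shade replicate 1. AT1G77200 encodes an AP2/ERF-type transcription factor. The other named falls were AT5G48490, AT1G67750, AT1G54820, AT5G17700 and AT4G26010, from -1.18 to -0.71, and AT4G26010 encodes a class III peroxidase. Each of these falls lost its call without a variance trend and without either wild-type white-light array.

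Of the 26 genes on the shade-induced list, 4 lay on a named probe set that was tested, which is what measured means here. Of these, 2 rose, IAA29 and YUC2 (3 adjusted over the list alone). The remaining genes may lie on probe sets without a single listed gene, so such counts do not describe a whole list. Of the auxin response list of 40 genes, 3 of 4 measured genes rose, and adjusted over the list alone 3 rose and 1 fell. The third was WES1 (GH3.5), at 0.76 ± 0.14 (adjusted p = 0.039). Its change ran from 0.632 to 0.889 over the alternatives. The call was lost with median scaling, with a replicate block, without the signal filter and without a variance trend. Leaving out any 1 array other than wild-type shade replicate 2 also ended it. None of the 11 measured cell wall growth genes passed over all genes, whereas 1 rose and 4 fell adjusted over the list alone. The gibberellin receptor gene GID1A was at 0.52 ± 0.14 (adjusted p = 0.192), and the light-harvesting gene LHCB4.2 at -0.34 ± 0.11 (adjusted p = 0.262), neither past the threshold. DFR, for an anthocyanin biosynthesis enzyme, was at -1.26 ± 0.28 (adjusted p = 0.089), and of the 5 flavonoid genes 0 passed over all genes and 1 fell adjusted over the list alone. The count of 63 was 3 by SAM (6 permutations), 4 without a variance trend, 26 without the signal filter and 31 on the wild-type arrays alone. Leaving out 1 array gave 22 or 30 (wild-type white light replicate 1 or 2), 33 (either bbx24 white-light array), 32 (wild-type shade replicate 1) or 225 (wild-type shade replicate 2). Without wild-type shade replicate 2 the excess of rises was gone, with 106 higher and 119 lower.

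In bbx24, the same question of a shade response gave both rises and falls. AT5G02580 rose by 2.52 ± 0.18 on the log2 scale (adjusted p = 8.11e-06), AT5G02540 by 2.14 ± 0.22 (adjusted p = 0.000557) and IAA29 by 1.85 ± 0.31 (adjusted p = 0.0116). EXPA8, an expansin gene of cell wall loosening, rose from 1133 ± 32.3 to 2829.8 ± 885 (log2 1.27 ± 0.22, adjusted p = 0.0135). Of the anthocyanin genes, 3 fell: AT4G14090, on the flavonoid list as the glucosyltransferase gene UGT75C1, went from 344 ± 41.6 to 50.0 ± 59.7. Its log2 change was -2.82 ± 0.48 (adjusted p = 0.0116), DFR was at -2.10 ± 0.28 (adjusted p = 0.00379) and UF3GT at -1.86 ± 0.39 (adjusted p = 0.0318). Without bbx24 shade replicate 1 these changes were -1.73, -1.49 and -0.95, and UF3GT no longer passed (adjusted p = 0.14). Without either bbx24 white-light array none of the 3 passed.

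The shade effect in bbx24 covered 248 probe sets, 93 higher and 155 lower. Other named genes with large rises were AT5G12050, THI2.2, AT1G73120 and AT1G62770, between 1.27 and 1.39. Large falls also occurred in AT1G57630, which encodes a TIR-domain protein, AT2G23270, AT1G14550, a class III peroxidase gene, AT4G37290, AT1G13650 and AT2G41730, between -2.46 and -1.87. Without bbx24 shade replicate 1 these 6 changes were between -1.57 and -1.02, and of them AT1G14550 alone passed. Without either bbx24 white-light array none of the 6 passed. On the shade-induced list 3 of 4 measured genes rose (3 adjusted over the list alone), HAT2, a homeodomain gene, by 0.65 ± 0.15 (adjusted p = 0.0464). On the auxin response list 3 of 4 rose (3 adjusted over the list alone). Of the 11 cell wall growth genes 2 rose, EXPA8 and EXLA1, and 3 fell, among them XTH18 at -0.85 ± 0.16 and EXPB3 at -0.77 ± 0.15, with 3 and 3 adjusted over the list alone. GRX480, a salicylate-induced glutaredoxin gene, fell by 0.75 ± 0.17 (adjusted p = 0.0449).

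Of the 5 measured flavonoid genes, 3 fell in bbx24 in shade, also adjusted over the list alone. The list shifted downward by camera (median -1.86, adjusted p = 0.00174), a call lost with an estimated correlation (adjusted p = 0.756 with an estimated correlation). The signal of AT4G14090 was 7.78 and 92.2 on the replicate 1 and 2 shade arrays of bbx24, that of DFR was 86.4 and 222, and that of UF3GT was 30.7 and 149. The median of the list is the value of UF3GT, and without bbx24 shade replicate 1 it was -0.95. The count of 248 was 8 by SAM, 7 without a variance trend, 58 without the signal filter and 506 on the bbx24 arrays alone. It was 9 or 24 without bbx24 white-light replicate 1 or 2, 28 without bbx24 shade replicate 1, and 408 or 401 without wild-type shade replicate 1 or 2. The balance of rises and falls turned with the setting: 33 were higher and 25 lower without the signal filter, and 5 and 2 without a variance trend. Without bbx24 white-light replicate 1 it was 9 and 0, and without replicate 2 it was 13 and 11.

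**Figure D1:**
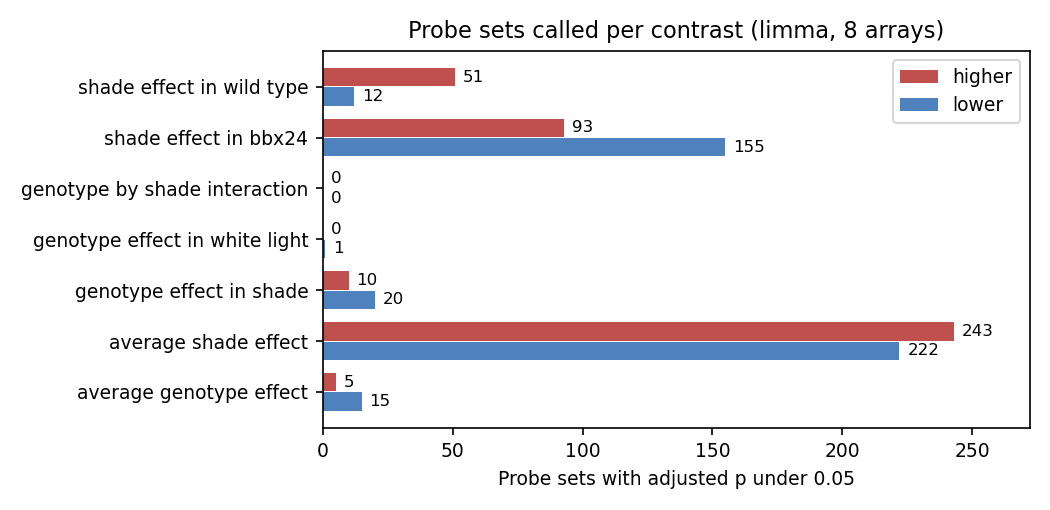
Number of probe sets with a limma adjusted p under 0.05 in each of the 7 contrasts, split into higher (red) and lower (blue) in shade or in bbx24. The average shade effect has 243 higher and 222 lower, and the interaction has 0.

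The 2 genotypes shared 41 of their shade calls, 35 higher and 6 lower in both, where independent lists would share 0.258 and 0.101. No array is common to the 2 contrasts, although they share the estimate of the spread. Of the 63 wild-type calls, 60 had the same sign in bbx24, and of the 248 bbx24 calls, 228 had the same sign in the wild type. Averaged over genotypes, 465 probe sets changed with shade, 243 higher and 222 lower.

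Averaged over genotypes, YUC2 rose by 1.07 ± 0.13 (adjusted p = 0.000619), HAT2 by 0.68 ± 0.10 (adjusted p = 0.00317), GID1A by 0.51 ± 0.10 (adjusted p = 0.0161) and BIM1, a brassinosteroid signalling gene, by 0.48 ± 0.09 (adjusted p = 0.0122). The plastid gene ndhF rose by 1.44 ± 0.22 (adjusted p = 0.0033). The median of 69 plastid-encoded probe sets, relative to the mean of all arrays, was -0.50 on wild-type shade replicate 1 and 0.47 on replicate 2. AT1G14550, AT1G13650, AT3G01430 and BGLU28, a beta-glucosidase gene, fell by 1.60, 1.54, 1.34 and 1.33 on the log2 scale. The flavonoid list shifted downward (median -1.31, adjusted p = 0.00288 by camera; adjusted p = 0.756 with an estimated correlation), with 3 of its 5 genes lower, also adjusted over the list alone. The cell wall growth, gibberellin and chlorophyll biosynthesis lists had adjusted p of 0.63, 0.795 and 0.266. Of the cell wall growth genes 2 rose and 3 fell (3 and 3 adjusted over the list alone). On the gibberellin list 1 rose, with 1 higher and 1 lower adjusted over the list alone. Of the 3 measured light-harvesting genes 0 passed over all genes and 3 were lower adjusted over the list alone. GI of the evening clock list was at 0.04 ± 0.10, and the reference gene PEX4 at 0.16 ± 0.10, neither past the threshold.

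The count of 465 for the average shade effect was 136 by SAM, 61 without a variance trend and 246 without the signal filter. Leaving out 1 array gave 241 or 270 (wild-type white light replicate 1 or 2), 142 or 173 (bbx24 white light replicate 1 or 2), 211 (bbx24 shade replicate 1) or 879 (wild-type shade replicate 2).

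**Figure D2:**
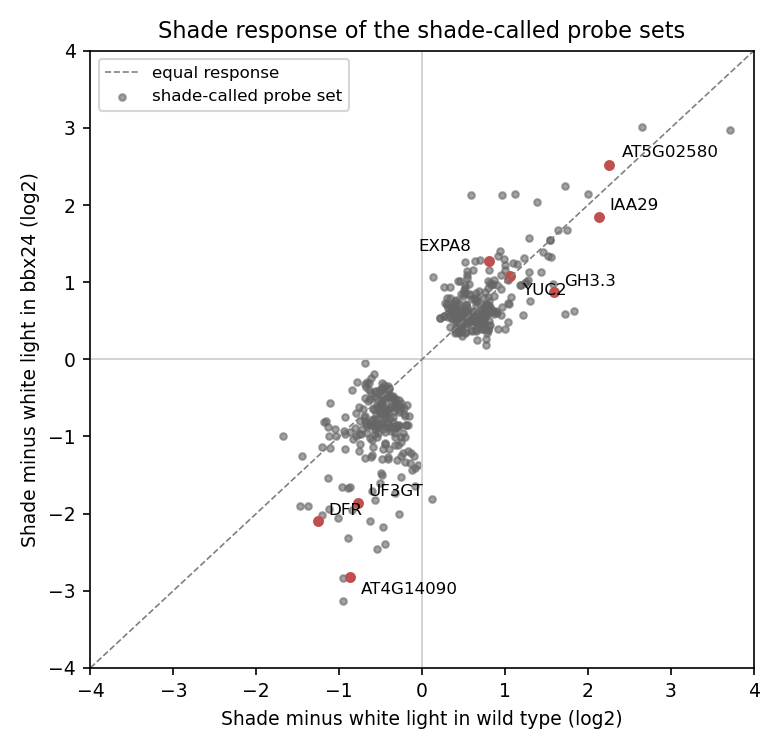
Log2 change from white light to shade in wild type (horizontal axis) and in bbx24 (vertical axis) for each of the 465 probe sets called for the average shade effect, with the line of equal response dashed and some named genes in red. Rising genes scatter around the line (medians 0.65 and 0.63). Falling genes lie mostly below it, at a median fall of 0.49 in wild type and 0.84 in bbx24. Relative to the mean of all arrays, falling genes had medians of -0.594 and -0.273 on bbx24 shade replicates 1 and 2.

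Whether shade acted differently in the mutant is the question of the interaction. No probe set passed the threshold by limma; 919 of 18391 had an unadjusted p under 0.05, where 920 would be expected by chance. The interaction was not run by SAM. The smallest p among named genes belonged to AT5G25240 and AT3G44140 (adjusted p = 0.163 for each), the latter with an interaction of 1.51 ± 0.23. AT5G25240 had signals of 160 ± 5.06 and 84.0 ± 13.2 in the wild type in light and shade, and 88.2 ± 11.1 and 219 ± 7.22 in bbx24. The class III peroxidase gene AT3G49960 was at 1.15 ± 0.20 (adjusted p = 0.371), AT3G23325 at -0.89 ± 0.18 and AT2G01300 at -1.92 ± 0.40 (adjusted p = 0.669 for each).

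Auxin and flavonoid genes did not pass either: GH3.1 was at 1.79 ± 0.57 (adjusted p = 0.834), GH3.3 at -0.72 ± 0.26 (adjusted p = 0.916) and AT4G14090 at -1.96 ± 0.67 (adjusted p = 0.867). Adjusted over the list alone, 1 auxin response gene was higher and 1 lower. The flavonoid list had a camera adjusted p of 0.1. The shade responses of bbx24 and the wild type are therefore not shown to differ gene by gene. Without wild-type shade replicate 1 or 2 the interaction had 2 calls or 1. Without bbx24 shade replicate 2 it had 77 calls, 3 higher and 74 lower, and the flavonoid list had an adjusted p of 1.18e-05.

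Over the 465 shade-called probe sets as a set, 35.1% had an interaction opposing their shade effect, and the signed fry test of limma gave an adjusted p of 0.594 over the 6 signed tests. The median response in the direction of shade was 0.56 in the wild type and 0.71 in bbx24, a ratio of 1.27. Taken apart after the data were seen, the 243 rising probe sets had medians of 0.65 and 0.63 (fry adjusted p = 0.84). The 222 falling ones had median falls of 0.49 and 0.84, with 79.3% falling further in bbx24 (fry adjusted p = 0.537). Relative to the mean of all arrays, their median was -0.594 and -0.273 on bbx24 shade replicates 1 and 2. On wild-type shade replicates 1 and 2 it was -0.244 and -0.168. The share opposing shade over all shade-called probe sets was 51.9% without wild-type white light replicate 2, 59.7% without wild-type shade replicate 2, and 20.7% without bbx24 shade replicate 2, where the unadjusted fry test passed.

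In white light, mutant and wild type differed by 1 probe set past the threshold, the unnamed probe set that was also lower in shade, so this call is not known to be of a gene other than BBX24. By unadjusted p, 813 were under 0.05, where 920 would be expected by chance, and SAM also called 1. None of the named genes passed. The smallest p-values were those of AT3G44140, at -1.06 ± 0.17 (adjusted p = 0.17), AT2G39980 at -0.80 ± 0.14, AT5G50310 at 0.90 ± 0.15 (adjusted p = 0.221 for each), AT5G26270 at 0.86 ± 0.16 (adjusted p = 0.366) and AT2G47780 at -1.71 ± 0.38 (adjusted p = 0.867). PAP85, a vicilin-like seed storage protein gene, was at -1.87 ± 0.50 (adjusted p = 0.992), and DFR at 0.36 ± 0.28 (adjusted p = 0.992). Of the 2 measured seed list genes 0 passed over all genes and both were lower adjusted over the list alone. IAA29 and YUC2 were at -0.26 ± 0.31 and -0.24 ± 0.18. Without wild-type white light replicate 1 the count was 2.

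In shade, AT2G29500, AT5G51440 and Hop3 were lower in the mutant and AT3G49960 and AT4G26010 were higher, genes placed together here by known function after their values were seen, with no set test. AT2G29500, for a small heat-shock protein, had 869 ± 466 in wild type and 191 ± 73.2 in bbx24 (mean signal ± SD, n = 2), a log2 difference of -2.04 ± 0.31 (adjusted p = 0.0235). AT5G51440, another small heat-shock protein gene, was at -1.71 ± 0.27 (adjusted p = 0.0235) and Hop3, a co-chaperone gene, at -1.32 ± 0.23 (adjusted p = 0.0437). AT2G29500 and Hop3 had their highest signals on the wild-type shade arrays. In white light AT2G29500 had 307 and 239 in wild type and 258 and 203 in bbx24. Hop3 had 526 and 310 in wild-type shade, 140 and 165 in bbx24 shade, and 139 to 220 in white light. AT5G51440 had its lowest signals in bbx24 in shade (196 and 453). The peroxidase genes AT3G49960 and AT4G26010 were higher by 0.92 ± 0.14 (adjusted p = 0.0235) and 0.82 ± 0.13 (adjusted p = 0.0285). In bbx24 the signal of AT4G26010 was about the same in shade (3742 and 3646) as in white light (3656 and 3544). Over the alternatives AT2G29500 ran from -2.602 to -1.475, AT5G51440 from -2.287 to -1.143 and Hop3 from -1.691 to -0.956. The peroxidases ran from 0.781 to 1.056 and from 0.707 to 0.925. Each of these calls was lost without the signal filter and without a variance trend. Each was also lost without wild-type shade replicate 1, bbx24 shade replicate 1 or either bbx24 white-light array. That of AT5G51440 was lost too without wild-type white light replicate 1, and that of Hop3 without either wild-type white-light array. Robust moderation also ended those of AT2G29500 and AT5G51440, and a replicate block those of AT5G51440, Hop3 and AT4G26010. Hop3 was also lost with the stricter filter. LCR67, a defensin gene of seeds, was lower in bbx24 at -4.02 ± 0.69 (adjusted p = 0.0342), with 993 and 135 on the 2 wild-type arrays and 4.36 and 12.4 on those of bbx24. As the bbx24 signals lie under the pseudocount, its size is not fixed: it ran from -5.44 to -2.65 over the alternatives. The call was lost with a pseudocount of 50, the stricter filter, no filter, robust moderation, no variance trend or a replicate block, and without wild-type shade replicate 1, bbx24 shade replicate 1 or either bbx24 white-light array.

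In all, 30 probe sets differed between the genotypes in shade, 10 higher and 20 lower in bbx24. Of these, 26 had the same sign in white light, where 1 of them passed. Further named genes higher in bbx24 were AT1G65570, a polygalacturonase-like gene, AT5G25240, AT3G50300 and AT5G11230, between 0.90 and 1.35. Lower ones were AT2G01300, BGLU27, AT4G28460 and AT5G01870, between -1.83 and -1.03. The single measured gene of the heat-shock list, AT5G48570 (ROF2), was at -0.87 ± 0.23 (adjusted p = 0.167). With 1 measured gene, adjustment over the list leaves the unadjusted limma p, which was under 0.05. Of the root list, 0 of 3 measured genes passed over all genes and 2 were higher adjusted over the list alone, EXPA18 at 0.83 ± 0.21 and EXPA7 at 0.65 ± 0.19, while PYK10 was at -0.07 ± 0.12. None of the 4 auxin response genes passed, GH3.3 being at -0.91 ± 0.18 (adjusted p = 0.0746), and adjusted over the list alone 1 was higher and 1 lower.

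The flavonoid list was lower in bbx24 in shade by camera (median -0.52, adjusted p = 0.0106; adjusted p = 0.756 with an estimated correlation). None of its 5 genes passed over all genes and 2 were lower adjusted over the list alone, with AT4G14090 at -1.86 ± 0.48 (adjusted p = 0.164). The list's call ended without wild-type shade replicate 1 or 2 (adjusted p = 0.138 or 0.0692) and without bbx24 shade replicate 1 (adjusted p = 0.452). The count of 30 was 2 by SAM, 15 with a replicate block, and 1 without a variance trend, without the signal filter or on the shade arrays alone. It was 8 without either bbx24 white-light array, 13 or 116 without wild-type shade replicate 1 or 2, and 3 or 140 without bbx24 shade replicate 1 or 2. A single array decided the balance: 76 were higher and 40 lower without wild-type shade replicate 2, against 15 and 125 without bbx24 shade replicate 2.

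**Figure D3:**
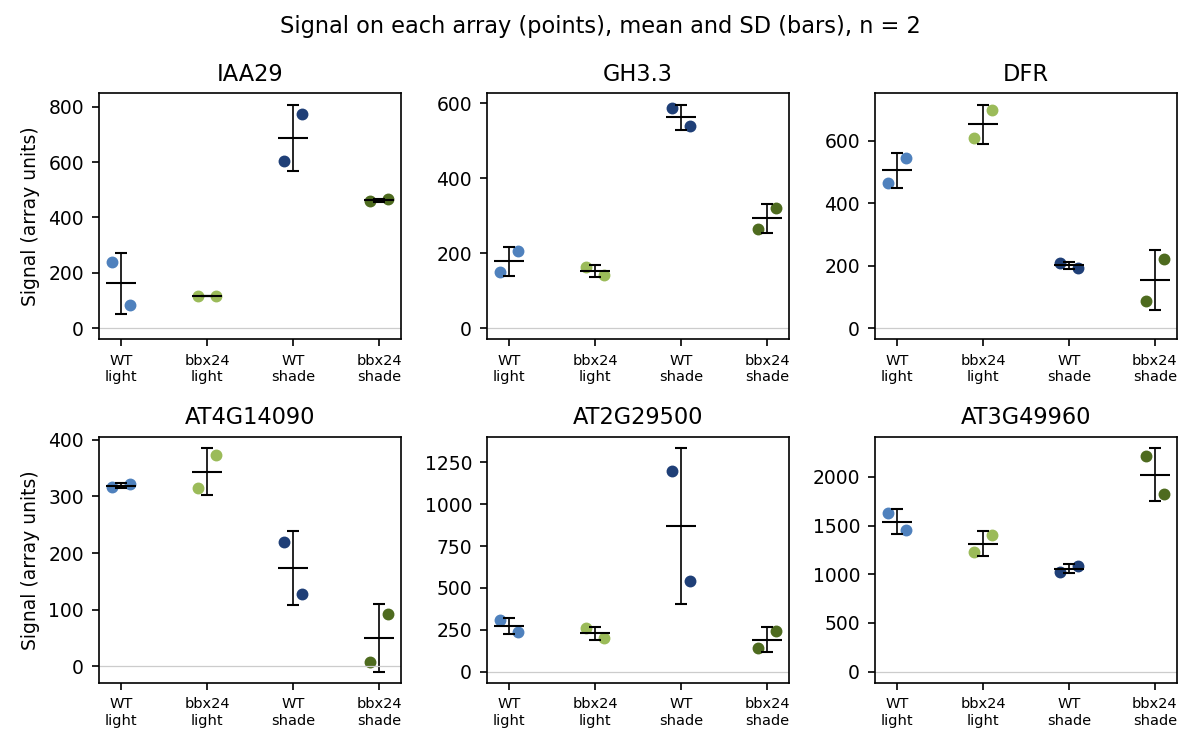
Signal in array units of 6 genes on each of the 8 arrays (points), with the mean and SD of each group of 2 (bars). IAA29 and GH3.3 are higher in shade, DFR and AT4G14090 are lower in shade, and in shade AT2G29500 is lower and AT3G49960 higher in bbx24 than in wild type.

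Averaged over both light treatments, 3 genes known from seeds were lower in bbx24, grouped here after their values were seen and with no set test. M17, a late embryogenesis abundant gene, was at -3.58 ± 0.55 (adjusted p = 0.0215) and LCR67 at -3.35 ± 0.48 (adjusted p = 0.0133). PAP85 was at -2.24 ± 0.35 (adjusted p = 0.0215). Over the alternatives M17 ran from -5.166 to -2.521, LCR67 from -4.268 to -2.521 and PAP85 from -2.661 to -1.712. All 3 calls were lost without the signal filter, without a variance trend and with robust moderation. All 3 were also lost without wild-type white light replicate 2, bbx24 shade replicate 1 or either bbx24 white-light array. That of PAP85 was lost without wild-type shade replicate 1 too. That of M17 was also lost with a pseudocount of 50. AT1G65570, AT5G26270 and AT5G11230 were higher, at 0.87 ± 0.15, 0.74 ± 0.11 and 0.67 ± 0.10 (adjusted p = 0.0427, 0.0215 and 0.0215). These 6 were the named genes among 20 probe sets, 5 higher and 15 lower. M17 varied strongly between wild-type replicates, with signals of 100.5 and 459 in white light and 1036 and 101 in shade, against 0.821 to 15.1 in bbx24.

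Of the seed list's 2 measured genes, PAP85 was lower and ICL, for isocitrate lyase of seed oil use, did not pass (both lower adjusted over the list alone). Of the 465 shade-called probe sets, 54.4% lay against their shade direction in the average genotype effect (fry adjusted p = 0.84). This joins 70.8% of the rising ones (fry adjusted p = 0.537) and 36.5% of the falling ones (fry adjusted p = 0.84), none past the threshold. The share over all shade-called probe sets was 41.5% without wild-type white light replicate 2 and 33.1% without bbx24 shade replicate 2, where the unadjusted fry test passed. The count of 20 was 2 by SAM and 1 without a variance trend or without the signal filter. It was 12 without wild-type white light replicate 2, 1 without either bbx24 white-light array, 99 without wild-type shade replicate 2 (56 higher and 43 lower), and 11 or 74 without bbx24 shade replicate 1 or 2.

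Any difference between the 4 groups was found for 296 probe sets by the moderated F test, 274 of which are in the authors' deposited table of 3255. That table also holds 60 of the 63 wild-type shade calls, 232 of the 248 in bbx24, 438 of the 465 for the average shade effect, 27 of the 30 genotype calls in shade and 14 of the 20 average genotype calls. Of the 3249 probe sets of the authors' deposited table that were tested, 1726 had an unadjusted F-test p under 0.05. The authors used SAM with settings not given in the sources used here, so the SAM-type count does not repeat their selection. The 296 became 6 by SAM, 8 without a variance trend and 54 without the signal filter. They became 168 or 187 without wild-type white light replicate 1 or 2, 63 or 78 without bbx24 white light replicate 1 or 2, 615 without wild-type shade replicate 2 and 125 without bbx24 shade replicate 1.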

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

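The additive model, the crossed block, the split into rising and falling genes and the symbol families were chosen after the data were seen; the other alternatives were planned. Quantile and median scaling, both pseudocounts, the stricter filter and robust moderation kept each count of calls within 1.5 times. Without the signal filter, the counts were 26 for the shade effect in wild type, 58 for the shade effect in bbx24, 1 for the genotype effect in shade, 246 and 1 for the average shade and genotype effects, and 54 for any difference. Without a variance trend they were 4, 7, 1, 61, 1 and 8, and by SAM-type relative differences 3, 8, 2, 136, 2 and 6. SAM was not run for the interaction. Fits on the 4 arrays of a contrast gave 31, 506 and 1 for the shade effects and the genotype effect in shade. The additive model gave 11 for the average genotype effect. The cause of these shifts was not tested.

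Deviations of same-numbered replicates correlated at -0.137 to 0.084 between groups, so the numbers were not taken to pair the arrays. A replicate block lowered the genotype effect in shade to 15 and kept the other counts within 1.5 times. With numbers crossed in wild-type shade, the blocked shade effect in wild type had 62 calls.

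Leaving out each array gave 22 to 225 calls for shade in wild type, 9 to 408 for shade in bbx24, 0 to 77 for the interaction, 1 to 2 for genotype in white light and 3 to 140 for genotype in shade. The ranges were 142 to 879 for average shade, 1 to 99 for average genotype, 63 to 615 for any difference and 2 to 6 for list tests. A lone array was then assumed to vary like the other groups. The 3 list calls became 0 with an estimated correlation and 0 with fry, and the symbol families gave 0. The share of shade-called genes opposing shade in the interaction was 50% on the fixed shade-induced list of 4 genes and ran from 20.7% to 59.7% without single arrays. For the genotype effect it was 50% on that list, 36.5% over falling genes, and 33.1% to 74.5% without single arrays. The value of 33.1%, without bbx24 shade replicate 2, turned the direction, past the unadjusted threshold of the fry test. With 7 arrays the contrasts are no longer independent, so choosing genes by their shade effect can shift these shares.

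Of 87 named gene and contrast pairs past the threshold, 0 changed sign and 9 stayed past it under every setting run for them. Without a variance trend 78 were lost, without the signal filter 58, with robust moderation 23 and with the block 16. Leaving out single arrays lost between 5 (wild-type shade replicate 2) and 60 (bbx24 white light replicate 1). Near the signal floor, as for M17, LCR67 and AT4G14090, the size of a fall is limited by background.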

Other observations

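The tests in this part were all chosen after the results were seen. Genes that share a symbol stem, and the plastid-encoded genes, were set against the contrasts as 39 families in 273 tests. None passed after adjustment. The smallest adjusted p, 0.064, was shared by 4 shifts: 6 IAA genes of auxin response upward in shade in the wild type (median 0.37), 41 UGT glycosyltransferase genes downward in the same contrast (median -0.18), 5 WRKY transcription factor genes downward in shade in bbx24 (median -0.43), and 69 plastid-encoded probe sets downward for the average shade effect (median -0.25). With an estimated correlation their adjusted p were 0.861, 0.861, 0.861 and 0.948. The IAA genes had a median of -0.43 for bbx24 against wild type in shade (adjusted p = 0.319).

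The 34 splits of the 8 arrays that an additive model could fit were compared for the average effects. For shade, 1 split, the real one, gave as many calls (438, with 1 as the highest of the others), and for genotype 1 split did so (11, with 1 as the highest other). For the flavonoid list in the average shade effect, 1 of 34 splits, the real one, gave as small a camera p (0.000326, with 0.0011 as the smallest other). For the 2 counts the real split ranked first, at a share of 2.94%, the smallest that 34 splits allow. The comparison was chosen after the calls were seen, so it does not exclude chance assignment of arrays. Without a variance trend or without the signal filter, the average genotype effect had 1 call. The flavonoid list was picked for this test after its p was seen among 28, and its adjusted p was 0.756 with an estimated correlation and 0.331 with fry, so its shift stays open.

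M17, LCR67 and PAP85 were lower in bbx24: the median of the 3 genes on each array, averaged over the 4 arrays of a genotype, differed by 3.14 log2 units. A candidate explanation is a differing amount of seed material among the wild-type harvests. In 6 of 6 gene-by-treatment pairs the wild-type replicates differed by more than the 95th percentile of 500 probe sets of like signal; for M17 the differences were 2.03 and 3.17 log2 units, and the percentiles 0.62 and 0.63. This is what that explanation, found from the same values, would give. The pairs are not independent, since the 3 genes were measured on the same arrays. All 3 were higher on wild-type white light replicate 2 and on wild-type shade replicate 1 than on the other replicate. ICL, on the fixed seed list and not picked for this difference, went the same way. Its signals were 693 and 3430 on wild-type white light replicates 1 and 2, and 1783 and 539 on the wild-type shade replicates. In bbx24 they ran from 338 to 544. An effect of genotype stays open: the exact two-sided permutation p over 4 against 4 arrays was 0.0286, the smallest this design allows. It was taken on M17, LCR67 and PAP85, which were chosen for the difference.

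AT3G49960 and AT4G26010 were higher in bbx24 than in wild type in shade. EXPA18, EXPA7 and both peroxidase genes had their lowest signals on the wild-type shade arrays. For AT4G26010 these were 1938 and 2257, against 3742 and 3646 in bbx24 in shade and 3100 to 3777 over the white-light arrays. AT3G49960 had 1027 and 1088 there, and its highest signals in bbx24 in shade (2214 and 1827). A larger share of root tissue in the bbx24 harvest would raise root genes alike, and EXPA18 and EXPA7 were higher by 0.83 and 0.65. PYK10, abundant in roots, had an upper 95% limit of 0.19 (log2), below the smaller peroxidase difference of 0.82. PYK10 alone goes against a larger root share, while EXPA18 and EXPA7 go with it, so root share stays undecided. A change within root hair cells was not tested. A shade response that differs between the genotypes stays open, since the smaller interaction adjusted p of the 2 genes was 0.371.

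The genotype effect in shade rose from 30 calls to 116 or 140 when either replicate 2 shade array was left out. A smaller fit alone is argued against, since leaving out any of the other 6 arrays lowered the count in 6 of 6 cases. A weaker shade response on the replicate 2 arrays may contribute: in 4 of 4 comparisons the shade-called genes had the smaller median response there. That test ran on genes chosen for their shade response, and of 4 fixed shade genes, HAT2, FHL, IAA29 and YUC2, 2 in wild type and 3 in bbx24 were lower on replicate 2, so it stays undecided.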
